A study of Mus musculus with 2 samples.

How the data were processed

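Small RNA of under 30 nt, made from total RNA of whole adrenal glands of 2 mice, was sequenced by the authors, with 1 library per animal, per the labels. The deposited files hold counts: whole numbers of reads per miRNA gene for mm10 with the GENCODE M21 annotation, per the files that describe each library. Each file has 3 count columns, which the values show to be reads without regard to strand, reads on the gene's strand and reads on the opposite strand. The aligner, the adapter trimming and their settings are not given in the sources used here. No normalization had been applied to the counts. All 2202 gene identifiers matched miRNA genes of GENCODE M21, which gave symbols, coordinates, hairpin sequences and overlapping genes of the same strand.

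The column for the gene's strand was used throughout, as it held the larger total of the stranded columns in both libraries. The 4 leading rows of each file name no gene and were kept out of library sizes and tests. They held 66.2% of the reads in replicate 1 and 69.0% in replicate 2: unaligned reads (33.5% and 30.2%), reads aligned to several places (26.2% and 28.8%), reads outside the annotated miRNA genes (6.44% and 10.0%), and a few ambiguous reads. Reads aligned to several places were thus not counted at genes. A mature miRNA encoded identically at several loci is undercounted by this, and the values of such genes are uncertain. Counting by strand mattered because 23 of the 259 miRNA genes with 100 or more counts in mean, among them Mir126a, Mir378a and Mir451a, overlap a miRNA gene on the other strand, and lose at least 90% of their counts without it. These 23 genes held 17.5% of the counts in replicate 1 and 14.2% in replicate 2.

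CPM were computed as counts divided by the total at miRNA genes, times 1e6. A gene was taken as detected at 2 CPM or more in both libraries. Values are given as mean ± SD of n = 2 or for each library, and shares of single libraries have exact Clopper-Pearson intervals at 95%. A limit of 3 counts was used for a count of 0. All samples belong to 1 group, so nothing was compared between groups and no quasi-likelihood test was possible. The 2 libraries were compared per gene by a two-sided exact binomial test, with the expected share from TMM effective library sizes, over genes with 10 or more counts in mean, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios are replicate 1 over replicate 2 after TMM scaling, with 0.5 counts added to each library, and their SE covers counting error. The biological coefficient of variation was the square root of the common dispersion of edgeR (estimateDisp, intercept only). Median log2 ratios of lists were set against 10000 random lists of detected genes matched on mean CPM. Genes with a copy number in their symbol were compared with other members of the same lists by a one-sided permutation test with 100000 resamples.

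The 19 gene lists, the 23 genomic clusters, the tests named above and most alternatives were fixed before the data were examined. So was the rule for named genes: the 20 genes with the highest mean CPM; up to 4 members of each list with the highest CPM, where detected; the 5 largest log2 ratios in each direction among genes past the exact test with 100 or more counts in mean; and the highest and lowest member of the 5 clusters with the most counts. Mir212, Mir98, Mirlet7f-2, Mir181c and Mir181d were named in addition, after their values were seen. Alternatives covered the unstranded counts, other denominators, pseudocounts, filters on low counts, DESeq2 size factors, total counts, a test with the common dispersion, and leaving out genes or 1 library.

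The tests were checked on simulated libraries with the real means and sizes. Among 389 unchanged genes the exact test called 0. With 100 genes changed 3-fold and 100 changed 1.5-fold, it recovered 94.0% and 77.8%, and called 6 unchanged genes. When simulated animals varied with a coefficient of 0.3, edgeR estimated 0.281 over 385 genes, and the exact test called 235 of them with no group difference at all. The counts were handled with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0, and figures were drawn with matplotlib 3.10.9.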

Results

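MicroRNAs (miRNAs) were profiled in the adrenal gland of male B6CASTF1/J mice aged 2 months. These mice are first-generation hybrids of an inbred laboratory strain and a strain derived from wild mice of the castaneus subspecies. The adrenal gland holds a steroid-producing cortex and a catecholamine-producing medulla, and the whole tissue was sequenced. The series holds 1 group of 2 libraries, from animals 3 (replicate 1) and 4 (replicate 2), which the labels give as separate biological replicates. It was made to evaluate RNA and has no second tissue, treatment or age, so the questions it answers are which miRNAs the gland held and how far 2 animals differed. Replicate 1 held 17000342 reads, of which 5752428 (33.8%) were counted at miRNA genes on the gene's own strand. Replicate 2 held 10752051 reads, of which 3333149 (31.0%) were counted there. A count of 0 allowed up to 0.522 CPM, the share of the counts at miRNA genes scaled to 1e6, in replicate 1 and 0.900 CPM in replicate 2. Of 2202 annotated miRNA genes, 372 reached 2 CPM in both libraries.

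Among reads counted at genes, the adrenal profile was led by the let-7 family, by the endothelial gene Mir126a and by Mir375. Mir375 is a miRNA gene best known from endocrine cells. Reads that aligned to several loci, 39.4% of aligned reads in replicate 1 and 41.2% in replicate 2, were not counted at genes. Genes of miRNAs encoded at several loci could thus rank higher, and the shares and ranks below are uncertain for this reason. Mirlet7g took 11.5% ± 0.187 of the miRNA counts (mean ± SD, n = 2), followed by Mirlet7b with 9.61% ± 0.182, Mir126a with 6.71% ± 0.284 and Mir375 with 5.75% ± 1.59. Mir378a, which lies in the gene of the mitochondrial regulator Ppargc1b, took 4.77% ± 0.846. The other members of the 10 most abundant genes were Mirlet7i, Mirlet7d, Mir23a, Mir23b and Mir10a. Together these 10 genes took 59.5% of the counts in replicate 1 and 56.2% in replicate 2, and the 20 most abundant genes took 76.3% ± 0.172. Genes 11 to 20 were Mir143, Mir139, Mir26b, Mir127, Mir22, Mir10b, Mir652, Mir322, Mirlet7e and Mir99a. For Mir375, counting error was small beside the difference between the animals. Its share was 6.88% in replicate 1 (95% Clopper-Pearson interval 6.86 to 6.90) and 4.62% in replicate 2 (4.60 to 4.65). Mirlet7g exceeded Mirlet7b 1.20-fold in replicate 1 and 1.19-fold in replicate 2, so this order held in both animals. The order of Mir126a and Mir375 was not settled: they were level in replicate 1 (1.01-fold) and 1.41-fold apart in replicate 2. All intervals and limits here cover only the counting error of reads taken as independent. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow.

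The leading genes lay in several kinds of host (mm10 coordinates, GENCODE M21). Mirlet7g was on chromosome 9 at 106178840 to 106178927 in an intron of Wdr82. Mirlet7b was on chromosome 15 at 85707319 to 85707403 in an exon of the long non-coding RNA Lncppara. Mir126a was on chromosome 2 at 26591357 to 26591429, inside an annotated exon of the endothelial gene Egfl7. Mir375 was on chromosome 1 at 74900658 to 74900721, outside other annotated genes of its strand. Mir378a was on chromosome 18 at 61397835 to 61397900 in an intron of Ppargc1b. Mir139 lay in an intron of Pde2a on chromosome 7 at 101475376 to 101475443, and Mir26b in an intron of Ctdsp1 on chromosome 1 at 74394310 to 74394394.

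Broadly expressed families made up much of the profile. All 12 annotated let-7 genes, whose products restrain growth and are abundant in adult tissues, were detected, and they summed to 32.3% ± 0.773 of the counts. The counts of its copied genes, such as Mirlet7a-1 and Mirlet7f-1, leave out reads that aligned to several loci. The 8 genes of the list of miR-10, miR-99, miR-100 and miR-125 were all detected and held 7.49% ± 0.569, led by Mir10a (33537 ± 2014 CPM), Mir10b (14097 ± 1133 CPM), Mir99a and Mir125a. Of 14 genes of miR-26, miR-30 and miR-29, 13 were detected, with 5.09% ± 1.07 of the counts, and Mir26b led at 15508 CPM in replicate 1 and 26258 CPM in replicate 2, before Mir29a, Mir30a and Mir30e. The growth-associated miR-17-92 list was far lower, at 0.610% ± 0.0639 with 12 of 16 genes detected. Its leading members were Mir93 (1939 ± 167 CPM), Mir17 (1473 ± 139 CPM), Mir92-1 and Mir106b. In these lists too, copied genes such as Mir26a-1, Mir26a-2 and Mir19b-1 leave out reads that aligned to several loci. The sums and the order of members, with Mir26b before Mir26a, are uncertain for this reason.

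Of the lists for endocrine tissue, the neuroendocrine list was led by Mir375 and the list for steroid-producing tissue by Mir132. The neuroendocrine list, which the medulla could supply, summed to 6.26% ± 1.51 with 8 of 9 genes detected. Mir375 made up most of it, and Mir7b, a miRNA of neuroendocrine cells, followed at 4243 ± 816 CPM. Mir375 exceeded Mir7b 18.8-fold in replicate 1 and 9.59-fold in replicate 2. Mir182 (337 ± 24.4 CPM) and Mir7-1 (265 ± 35.4 CPM) were lower. Mir7-1 is a copied gene, and its counts leave out reads that aligned to several loci, so its place in this order is uncertain. All 11 genes of the list reported for steroid-producing tissue were detected and summed to 4572 ± 1194 CPM. Its leading members were Mir132 (1432 ± 23.7 CPM), Mir214 (1119 ± 544 CPM), Mir27a (1051 ± 413 CPM) and Mir182. The copied genes Mir24-1 and Mir24-2 of this list leave out such reads as well. Mir132 and Mir212, which share a locus, differed 38.6-fold in replicate 1 and 16.5-fold in replicate 2.

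Genes typical of the other cell types in the gland were found at graded levels. Mir126a gave the endothelial list nearly all of its 6.71% ± 0.284. Smooth muscle and mesenchymal genes held 3.42% ± 0.0935, and nearly all counts of the list came from Mir143 (31829 ± 77.7 CPM). Mir145a had 1209 ± 318 CPM, Mir214 1119 ± 544 CPM and Mir199b 16.3 ± 6.02 CPM. The hairpin of Mir199b shares 20 bases with 2 other miRNA genes, and reads that aligned to several loci were not counted. Its level and the part of Mir143 in this list are uncertain for this reason. White blood cell genes summed to 3104 ± 208 CPM, with Mir146 at 1498 ± 34.0 CPM, Mir150 at 794 ± 150 CPM, Mir142 at 391 ± 0.366 CPM and Mir155 at 322 ± 5.99 CPM. Neuronal genes summed to 793 ± 182 CPM with 8 of 19 detected. Mir137 led (468 ± 88.9 CPM) before Mir138-1, Mir129-2 and Mir153. The copied genes of Mir124a and Mir9 were not detected, but reads that aligned to several loci were not counted at genes. The sum and order of the neuronal genes are therefore uncertain. The epithelial miR-200 family was the lowest of these lists, with a sum of 54.5 ± 5.33 CPM over its 5 genes. Mir200c alone reached 32.6 ± 8.74 CPM, and Mir429, Mir200b and Mir141 lay between 6.01 and 6.49 CPM on average.

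Each list for a neighbouring or other tissue held less than 1% of the counts. The brown adipose list summed to 1919 ± 73.0 CPM, led by Mir455 (1609 ± 94.1 CPM) and Mir193b (272 ± 9.18 CPM), with Mir365-2 and Mir365-1 at 30.1 CPM or less in both libraries. Mir122, the main miRNA of hepatocytes, had 690 CPM in replicate 1 and 1331 CPM in replicate 2. The kidney-enriched list reached 119 ± 30.7 CPM in sum, with Mir204 at 57.2 ± 20.5 CPM, Mir194-2 at 29.0 ± 0.631 CPM, Mir192 at 27.5 ± 9.89 CPM and Mir215 at 4.23 ± 0.896 CPM. None of the 19 genes of the testis-expressed miR-506 region on the X chromosome had a count in either library. Copied genes of these lists, such as Mir365-1 and Mir194-2, leave out reads that aligned to several loci.

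**Figure D1:**
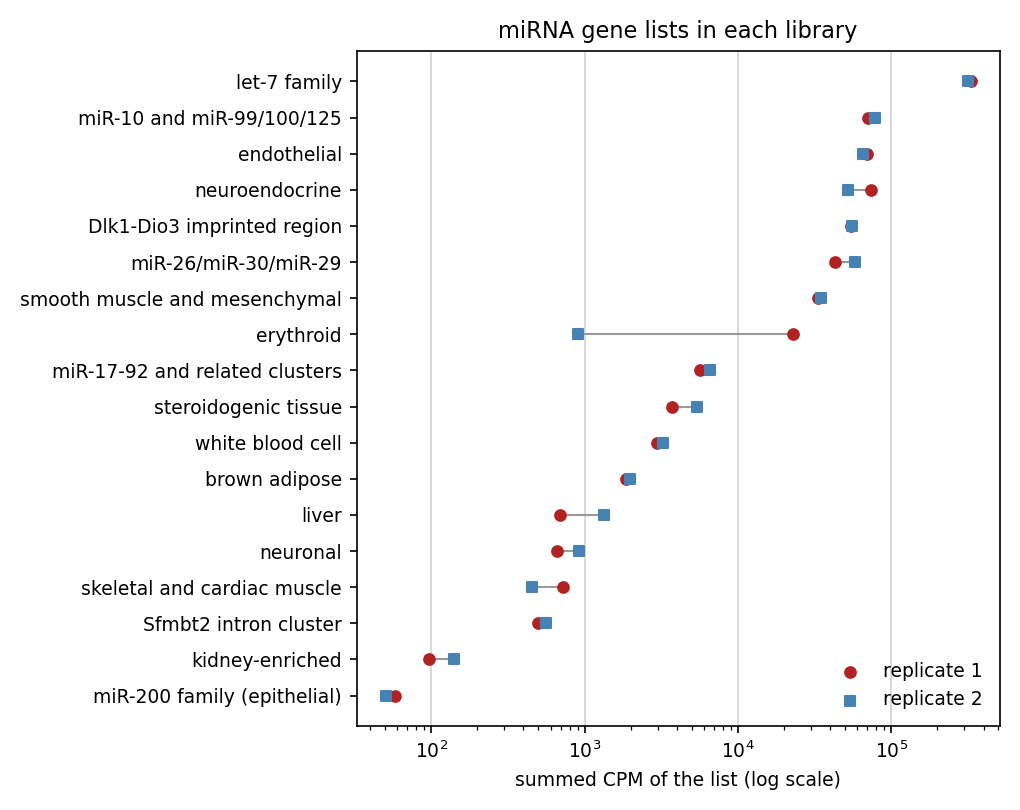
Summed CPM (log scale) of each fixed gene list in replicate 1 (circles) and replicate 2 (squares), with a line joining the 2 libraries of a list; the miR-506 region list, at 0, is left out. The let-7 family is highest at 32.3% of the counts on average, and the erythroid list shows the widest gap, from 22813 CPM in replicate 1 to 901 CPM in replicate 2.

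The lists for imprinted miRNA clusters differed in counted level. The Dlk1-Dio3 region on chromosome 12, expressed from the maternal chromosome, held 5.53% ± 0.0741 of the counts, and 45 of its 52 listed genes were detected. Mir127 was its highest member at 17696 ± 577 CPM, followed by Mir379 (6177 ± 1889 CPM), Mir411 (5802 ± 1249 CPM) and Mir541 (5114 ± 439 CPM, in an intron of the long non-coding RNA Mirg). The list for the large cluster in an intron of Sfmbt2, best known from placenta, was set by gene name and not by position. It had 7 of 81 genes detected and a sum of 528 ± 47.2 CPM. Mir467d led the list with 244 ± 11.6 CPM, before Mir467e (116 ± 15.2 CPM), Mir669c (86.0 ± 7.47 CPM) and Mir669o (43.1 ± 10.8 CPM). These named genes lie in an intron of Sfmbt2, and the position of the others was not checked. Hairpins of the Sfmbt2 list share sequence, and reads that aligned to several loci were not counted at genes. The counts are thus lower limits for the family. The CPM are uncertain in either direction, since the total leaves out such reads too.

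Members of the same genomic cluster, which can share a primary transcript, were counted at very different levels. In 15 of 23 clusters the highest member exceeded the lowest more than 4-fold in both libraries. In many of these, such as those of Mir29b-1 and Mir125b-2, the lowest member carries a copy number. Counts of such genes leave out reads that aligned to several loci, so the number of uneven clusters is uncertain. Among the 5 clusters with the most counts, Mir23b exceeded Mir24-1 by 9.31 ± 0.05 on the log2 scale (mean ± SD, n = 2), Mir23a exceeded Mir24-2 by 7.76 ± 0.81, Mirlet7d exceeded Mirlet7f-1 by 7.06 ± 0.11 and Mirlet7b exceeded Mirlet7c-2 by 5.42 ± 0.26. The lower gene in each of these 4 pairs carries a copy number, and its mature product is encoded at more than 1 locus. Mir143 exceeded Mir145a by 4.74 ± 0.38, and neither has a second copy in its symbol. Clusters with evenly counted members were also present. Mir98 exceeded Mirlet7f-2 by 0.19 ± 0.09, though Mirlet7f-2 also carries a copy number. Its counts leave out reads that aligned to several loci. The order of Mir181c and Mir181d turned between the animals, with 650 and 763 CPM in replicate 1 and 1012 and 866 CPM in replicate 2.

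**Figure D2:**
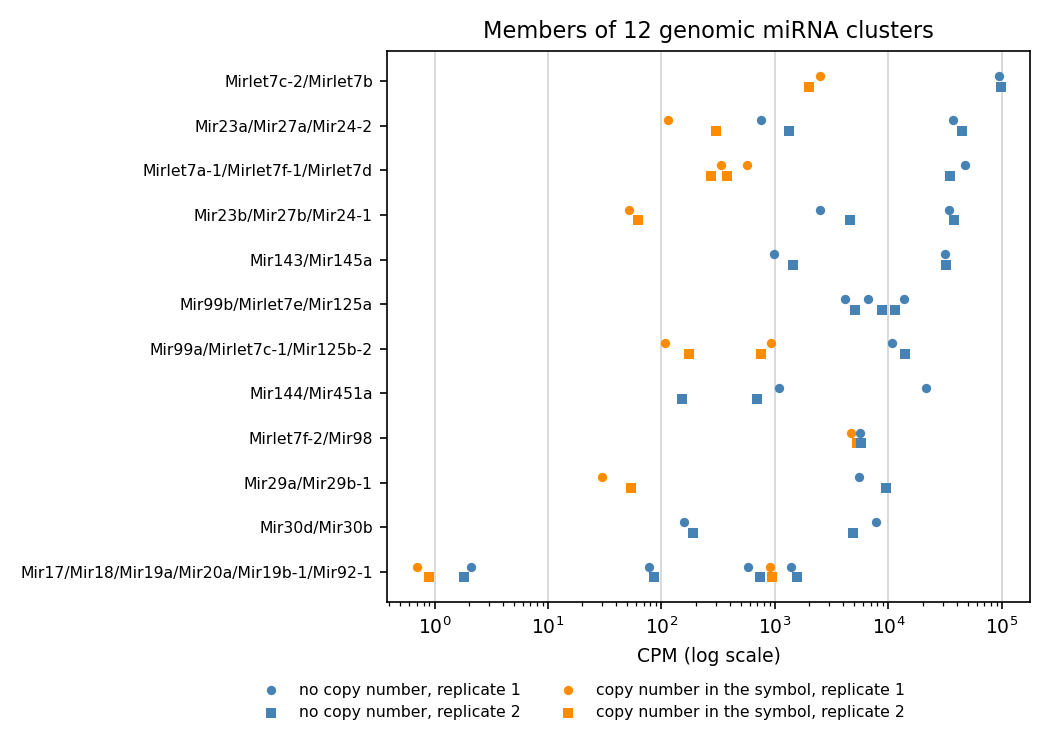
CPM (log scale) of each member of the 12 fixed genomic clusters with the highest summed CPM, in replicate 1 (circles) and replicate 2 (squares); orange marks genes with a copy number in the symbol and blue the others. Mir24-1 (56.8 CPM on average) and Mir24-2 (209 CPM) lie far below Mir23b (36038 CPM) and Mir23a (40652 CPM).

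The 2 animals shared 1 overall profile. Across the 389 miRNA genes with 10 or more counts in mean, Pearson's r of log2(CPM + 1) was 0.977 and Spearman's rho was 0.972; genes are not independent replicates, so no p is given. Of these genes, 333 (85.6%) lay within 2-fold of each other after TMM scaling. The biological coefficient of variation estimated by edgeR was 0.361 (95% bootstrap interval 0.305 to 0.418). That bootstrap resampled genes of these 2 libraries, so the interval does not cover the choice of animals. The exact binomial test, which compares these libraries and not conditions, found 230 of the 389 genes to differ beyond counting error (two-sided, Benjamini-Hochberg adjusted). Of these, 120 were higher in replicate 1 and 110 were lower. The test takes reads as independent molecules, so it can call too many genes. TMM scaling moved log2 ratios up by 0.20 against total counts; by total counts 85 of 255 such genes were higher in replicate 1. With a common dispersion estimated from the same 2 libraries, edgeR's exact test called 4 genes: Mir451a, Mir499, Mir144 and Gm26117. It sets 1 library against 1, so no spread within either side enters it.

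Red blood cell miRNAs and miRNAs of myosin genes were much higher in replicate 1. Mir451a, an erythroid miRNA, had 21615 CPM in replicate 1 and 695 CPM in replicate 2, a log2 ratio of 5.16 with a counting error of 0.03 (SE). Its neighbour Mir144 on chromosome 11 had 1084 and 150 CPM (log2 ratio 3.05), and Mir486, the remaining erythroid gene detected, had 113 and 55.2 CPM (1.23). All 3 detected erythroid genes were higher in replicate 1, under TMM, DESeq2 and total-count scaling alike, also when adjusted over the list alone. The list held 22813 CPM in replicate 1 and 901 CPM in replicate 2, so its mean rests on replicate 1. In the muscle list, Mir499, in an intron of the myosin gene Myh7b, had 423 and 23.1 CPM (log2 ratio 4.38), and Mir208b, in an intron of Myh7, had 204 and 40.8 CPM (2.51). Mir206, a miRNA of skeletal muscle, went the other way, with 81.7 CPM in replicate 1 and 389 CPM in replicate 2 (log2 ratio -2.05). Of the 4 tested genes of the muscle list, 3 were called higher in replicate 1 and 1 lower. The list of 11 genes summed to 720 CPM in replicate 1 and 457 CPM in replicate 2. Copied genes of this list, those of Mir1a and Mir133a, leave out reads that aligned to several loci, so the sums are uncertain. Mir1839, whose hairpin overlaps an annotated small Cajal body RNA, was the remaining gene of the 5 largest differences towards replicate 1 (log2 ratio 1.71).

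In the other direction, Gm26117 had 16.7 CPM in replicate 1 and 558 CPM in replicate 2 (log2 ratio -4.86, SE 0.15). This annotated miRNA gene lies on chromosome 15 at 74563821 to 74563915, overlaps in part an exon in the untranslated region of Adgrb1, and has a GC content of 91.6%. Mir223, a miRNA of myeloid cells, had 36.7 and 159 CPM (-1.92). Mir222 had 80.7 and 327 CPM (-1.82), and Mir6538 had a log2 ratio of -1.71. For the 10 genes with the largest differences, the highest adjusted p of the exact binomial test was 5.09e-29. With 1 library on each side, none of these differences has a replicate check.

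**Figure D3:**
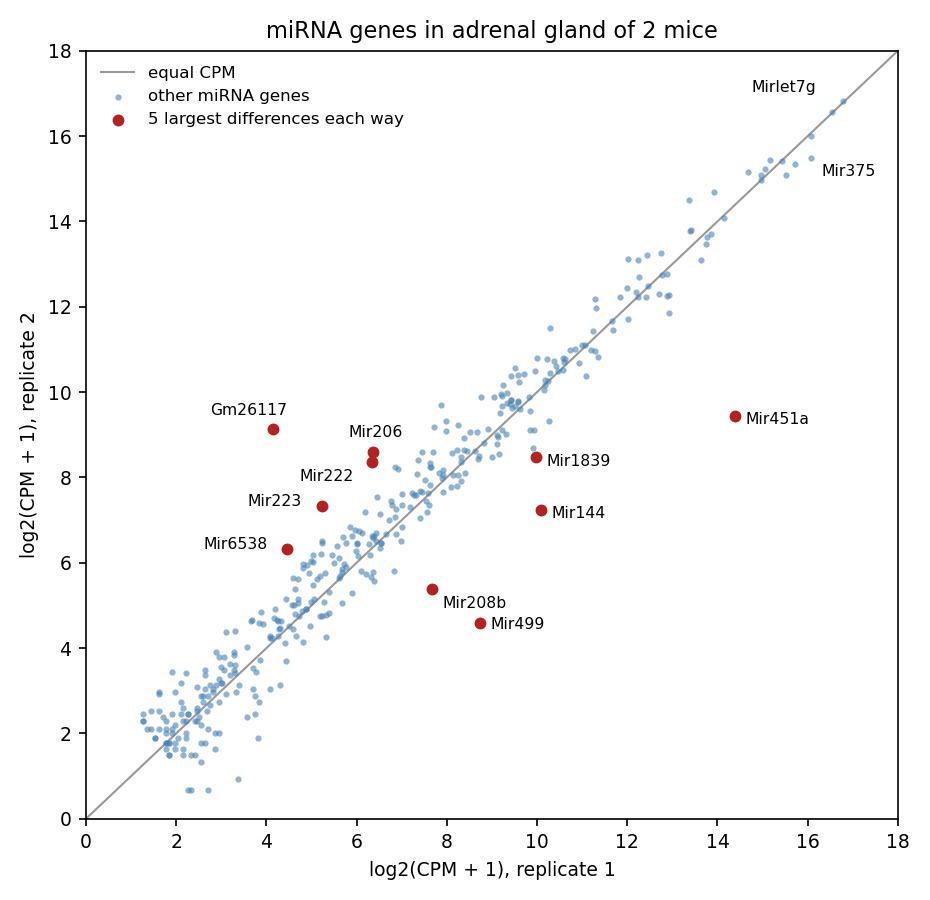
Log2(CPM + 1) of each miRNA gene with 10 or more counts in mean, replicate 1 against replicate 2; the grey line marks equal CPM, and red points are the 5 largest differences in each direction by the rule fixed for named genes. Most genes lie near the line (r = 0.977), with Mir451a, Mir499, Mir144 and Mir208b far towards replicate 1 and Gm26117 far towards replicate 2.

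Smaller differences went both ways in most lists with several calls. All 12 let-7 genes were called higher in replicate 1 over all genes tested, and all 12 when adjusted over the list alone, with a median log2 ratio of 0.47. That median lay at percentile 99.0 of 10000 random lists of the same size matched on CPM. By total counts 8 let-7 genes were called higher and 4 lower. Among the 4 were Mirlet7g (113646 CPM in replicate 1 and 116286 in replicate 2) and Mirlet7b, the genes with the most counts. The direction of the members with the smallest ratios thus depended on the scaling. In the Dlk1-Dio3 region 21 of 45 tested genes were called lower in replicate 1, 11 higher and 13 neither; adjusted over the list alone the counts were 22 lower and 11 higher. Its median log2 ratio was -0.25, at percentile 1.19. By total counts 30 were lower and 10 higher, with a median of -0.45. Mir379 (log2 ratio 0.83) and Mir127 (0.27) were higher in replicate 1 and Mir411 (-0.24) lower. In the steroid-tissue list 5 of 11 genes were called lower in replicate 1 and 2 higher, with Mir214 at -0.84 and Mir27a at -0.62; its median was at percentile 6.26. By total counts these were 7 lower and 1 higher. The neuroendocrine list had 3 genes higher and 2 lower, with Mir375 at 0.77 and Mir7b at -0.20, but by total counts 3 were higher and 4 lower, and its median log2 ratio turned from 0.11 to -0.09. White blood cell genes split, with 3 higher and 2 lower, and by total counts 0 were higher and 2 lower. The 4 brown adipose genes were called higher in replicate 1, but by total counts 2 were higher and 1 lower. Of 8 tested neuronal genes 1 was called higher and 4 lower, and Mir122 was lower (log2 ratio -0.75). By total counts the neuronal genes gave 0 higher and 5 lower. The remaining lists had 4 higher and 3 lower for miR-10, miR-99, miR-100 and miR-125, 5 and 4 for miR-26, miR-30 and miR-29, 1 and 3 for miR-17-92, 2 and 2 for smooth muscle, 0 and 2 for kidney, 1 and 2 for Sfmbt2, 1 and 0 for the miR-200 family and 1 and 0 for the endothelial list. By total counts these became 2 and 6 for the first list, 4 and 5 for miR-26, miR-30 and miR-29, 0 and 8 for miR-17-92, 1 and 2 for smooth muscle and 0 and 4 for Sfmbt2, with no change for the kidney, miR-200 and endothelial lists. Apart from the Dlk1-Dio3 region, counts adjusted over the list alone equalled those over all genes tested.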

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

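The tests on shared bases, on copied genes without the Sfmbt2 list, on transcription of copied loci, on Mir451a and the genes that went with it, and on GC content and abundance were chosen after the results were seen; the main test on copied genes and the test on scale factors were fixed before.

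Reads aligned to several places drew attention as a signal outside the counted genes: they made up 39.4% of aligned reads in replicate 1 and 41.2% in replicate 2. For each read counted at a miRNA gene there were 0.775 such reads in replicate 1 and 0.929 in replicate 2. Reads on the strand opposite to a miRNA gene, where no miRNA gene is annotated on that strand, were few, at 0.00417% and 0.00897% of the same-strand counts. They exceeded the 3 counts that a count of 0 allows for a gene, in both libraries, at 5 genes: Mir203 (124 and 190), Mir708 (20 and 25), Mir130a (12 and 7), Mirlet7b (11 and 25) and Mir34b (7 in each).

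Genes with a copy number in their symbol had low counts. In the fixed lists, 95 such genes had a median log2(CPM + 1) that was lower by 5.73 than that of the 188 others (difference -5.73; one-sided permutation p = 1e-05, the smallest that the resamples can give). The loss of reads that align to several loci predicts this. Without the Sfmbt2 list the difference was -2.42 (permutation p = 0.0097), and -2.49 (permutation p = 0.0021) where 20 shared bases replaced the copy number. For shared bases over all 389 genes with 10 or more counts in mean it was -0.41 (permutation p = 0.25). That filter removes the genes with the fewest counts. Low transcription of those loci is argued against by their neighbours: in 11 clusters, 14 copy-numbered genes lay at a median log2 difference of -5.76 from single-copy genes of the same cluster (95% bootstrap interval -7.06 to -3.89), and 12 of the 14, all but Mir92-1 and Mir194-2, lay below all of them. Members of clusters without a copy-numbered gene also differed, by 0.23 (Mir181c and Mir181d) to 5.16 (Mir30d and Mir30b) on the log2 scale. Differences in processing or stability between hairpins were not tested and stay open. With 1 group, no explanation could be tested between groups.

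Mir451a, Mir144, Mir499 and Mir208b were higher in replicate 1. They were chosen for their size, so a test on them is no independent check; counting error is still argued against, because the adjustment covers all 389 tested genes and the smallest of the 4 ratios, 2.51 on the log2 scale for Mir208b, had an adjusted p of 3.05e-125 (two-sided exact binomial test). More blood in the tissue of replicate 1 is a candidate explanation for Mir451a and Mir144, but the median log2 ratio of the white blood cell list was 0.16, over members from -1.92 (Mir223) to 0.25 (Mir146), which leaves it open. RNA or reads of heart or slow muscle could account for Mir499 and Mir208b; the heart miRNA gene Mir208a (54 counts in replicate 1 and 3 in replicate 2) goes with it, while Mir206, a miRNA of skeletal muscle, had a log2 ratio of -2.05. No heart library was analysed here, and counts of Mir1a and Mir133a leave out reads with several loci, so this cannot be told apart from a difference between the animals.

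Most tested genes differed between the libraries beyond the counting error of reads taken as independent. Neither GC content of the hairpin (Spearman's rho across 389 genes 0.0101, 95% bootstrap interval -0.09 to 0.11) nor abundance (0.00597, -0.10 to 0.11) followed the log2 ratio, which argues against either as a trend behind the differences. In the test on scale factors, at least 237 genes were called under DESeq2 size factors and under total counts. DESeq2 ratios lay near the TMM ones (5.14 and 5.16 for Mir451a), so this number alone decides little. TMM and DESeq2 factors centre the ratios (median log2 ratio 0.0072 by TMM), so the near-even split of their calls was set by the scaling. A single wrong scale factor would shift all genes the same way. Calls in both directions remained under each scaling, which argues against such a factor as the only source of the differences. In replicate 1, 120 genes were higher and 117 lower by DESeq2 size factors, and 85 and 170 by total counts. Whether the animals or the handling of their tissue made the difference stays open, with 1 library per animal.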

How the results depend on the processing

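Alternatives that leave out 5 genes, that leave out the Sfmbt2 list or that replace the copy number by shared sequence were chosen after seeing the data. Of 50 alternative values for the summary results, 39 stayed within the spread or the limit set for them. Leaving out each library in turn moved Mirlet7g from 11.4% to 11.6%, detected genes from 388 to 401 and the 10 leading genes from 56.4% to 59.5%. Without regard to strand, Mirlet7g took 13.7% and the 10 leading genes 62.7%, because overlapping genes such as Mir126a lose their counts. With all reads as the denominator these became 3.73% and 18.8%, by construction. Counting genes with 1 count or more in both libraries gave 583 detected genes. Pearson's r was 0.985 with no filter and 0.961 for genes with 100 or more counts in mean, while Spearman's rho was 0.908 and 0.947. The cause was not tested. The biological coefficient of variation stayed between 0.347 and 0.372 under other scalings, filters and columns, and was 0.293 without Mir451a, Mir144, Mir499, Mir208b and Gm26117. The exact binomial test called between 200 and 255 genes, with more than 50% higher in replicate 1 except by total counts (33.3%) and without Mirlet7g (49.8%). The exact test of edgeR with the common dispersion called 4 genes, and 16 at an unadjusted p under 0.05, since it sets each gene against the spread of all genes between the same libraries. Lists with 1% of the counts or more went from 8 to 4 without the leading member of each, and were 7 to 8 without 1 library. The low counts of copy-numbered genes kept their direction: the difference was -2.42 without the Sfmbt2 list (permutation p = 0.0097), and for members of the fixed lists that share 20 bases with another gene it was -6.61, or -2.49 without the Sfmbt2 list (permutation p = 0.0021). Over all 389 genes with 10 or more counts in mean it was -0.41 for shared bases (p = 0.25 by permutation), but that filter selects on the counts themselves and removes the genes with the fewest. Of the 124 values for single lists and named genes, 98 moved by less than 1 SD or kept their call and 26 moved further, 17 of these by leaving out a list's leading member and 9 without regard to strand. The erythroid list counts among the 98 only because its SD (15494 CPM) exceeds its mean (11857 CPM): it held 901 CPM without replicate 1, 745 CPM without regard to strand and 701 CPM without Mir451a. No log2 ratio of the 10 genes with the largest differences changed direction or lost its call under another scaling. Depth limited genes under about 1 CPM, where 3 counts are 0.522 CPM in replicate 1 and 0.900 CPM in replicate 2.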

Other observations

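The genes and sets in this part were chosen after their values were seen. Of the 6 genes of the miR-34 family, known as targets of p53 and taken here with the Mir449 genes, 4 were detected in both animals: Mir34c had 1406 ± 538 CPM and Mir34a 1156 ± 6.25 CPM (mean ± SD, n = 2), with Mir34b and Mir449a lower, and the 6 summed to 2681 ± 582 CPM. The X-linked cluster of Mir322, Mir503, Mir351, Mir542 and Mir450 genes held 14784 ± 2616 CPM, of which Mir322 had 12635 ± 2336 and Mir351 1647 ± 175. All 7 of its genes were detected. miRNA genes in the Hox regions were all detected, with Mir615 at 1860 ± 221 CPM, Mir196b at 279 ± 56.0 CPM and Mir196a-2 at 195 ± 4.80 CPM beside the abundant Mir10a and Mir10b.

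Other miRNA genes in imprinted regions spanned a wide range. Mir335, in the Mest gene region, had 3239 ± 9.95 CPM. Mir298 had 959 CPM in replicate 1 and 410 CPM in replicate 2, and its neighbour Mir296 had 273 and 218 CPM. Mir483, from the Igf2 gene region, had 11.8 and 24.3 CPM, and Mir675, from H19, had 1 count in each library.

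Genes of the clusters typical of pluripotent stem cells were counted at low levels in both animals. Mir294 had 145 counts in replicate 1 and 115 in replicate 2 (25.2 and 34.5 CPM), Mir292 had 133 and 70, and Mir293 had 76 and 77. Mir302a had 71 and 15 counts, Mir302b 75 and 9, and Mir302d 63 and 14. In all, 6 of 14 such genes reached 2 CPM in both libraries. Of 11 genes that were called different by the exact binomial test and at least 4-fold apart, 9 were higher in replicate 1; beside those named in the report these were Mir208a (54 and 3 counts), Mir302b, Mir1948 (32 and 2), Mir3060 (23 and 2) and Mir6900 (22 and 2).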
